A study of Mus musculus with 4 samples.

How the data were processed

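The study sequenced RNA from testis cells of 7-day-old C57BL/6 mice, in 2 libraries of RNA immunoprecipitated with a DDX20 antibody and 2 libraries of input RNA (10% of total RNA). Per the labels' protocols, cells were crosslinked with 200 mJ per square cm of 254 nm light, lysed and precipitated, and libraries were made with the NEBNext Ultra RNA kit, which does not mark strand, and sequenced as 150-nt read pairs. The labels of the RIP samples give antibody catalogue numbers that differ in 1 character. Group and replicate were taken from the sample titles.

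The deposited table holds raw read counts per gene, with 55357 gene identifiers and 1 column per library. Per the submitters' processing notes, Trimmomatic 0.36, cutadapt 4.1, STAR 2.7.2b, SAMtools and featureCounts were used with GRCm38; their order and settings are not given in the sources used here, nor is the annotation release. Most nonzero counts are even (65.37% to 67.40% per library), and a count of 2 is more frequent than a count of 1 in each library (2906 against 554 genes in input 1), as arises when both mates of a pair are counted. Counting pairs as 2 reads overstates the depth behind each value. Symbols, lengths and coordinates were taken from the GENCODE M21 annotation of GRCm38, which names 52081 (94.1%) of the identifiers; only 35 of these carry the same version number, so the counted gene models can differ from those whose coordinates are given. Zfp469 is an example, since M21 lists it as a long noncoding RNA.

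Totals were 21913977 and 21416567 counts for input and 38458014 and 37927689 for RIP. The identifier ENSMUSG00000119584, which has no symbol in the annotation used, held 1.43% and 1.395% of input counts and 0.828% and 0.855% of RIP counts. Replicates were compared by a chi-square test of their halved counts over genes with a sum of at least 20. The median statistic was 1.171 times that of sampling noise for input and 1.145 times for RIP, against 46.1 and 42.6 between a RIP and an input library. Replicates therefore differed slightly more than counting noise and were kept as separate samples. The common biological coefficient of variation was 0.0320.

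Genes were kept by filterByExpr and scaled by TMM, with factors of 1.127, 1.130, 0.880 and 0.892. RIP was tested against input with edgeR 4.0.16 (robust quasi-likelihood fit and test) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05; enriched genes also had a fitted log2 fold change of at least 1. Standard errors are the fold change divided by the square root of the test's F statistic. Gene lists were tested with camera on limma-voom values (limma 3.58.1). Pipeline steps were checked on simulated data drawn from the real means and library sizes, with 50 genes changed at each fold and read pairs counted as 2. Of genes changed by 1.5-, 2-, 4- and 8-fold between RIP and input, edgeR recovered 52%, 74%, 88% and 98%, with 6 unchanged genes called of 17422 tested. Camera called 0 of 100 random unchanged lists at an unadjusted p of 0.05. Their genes were simulated independently, so this does not test camera on lists of correlated genes. A simulated length trend gave 6496 calls before and 0 after the length offset. That trend was the only difference simulated and the offset was fitted to it, so this checks only that the offset works as written. In the real data 12144 of 17357 genes were still called after it.

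Before the data were examined, the tests, most alternatives, 27 gene lists and the rule for named genes were fixed. That rule took the 10 largest increases and the 10 largest decreases among called genes with a mean CPM of at least 10 and no overlap between RIP and input libraries, leaving out predicted genes, pseudogenes and identifiers without a symbol; it took the 2 called members of each list with the highest mean CPM per direction (or, where none was called, the 2 with the highest mean CPM), all members of the SMN complex and Ddx20. The lists cover the SMN complex, Sm and LSm proteins, SR proteins and hnRNPs, small RNAs and their host genes, nuclear long noncoding RNAs, cell cycle phases, germ cell stages, Sertoli, Leydig, stromal, endothelial, macrophage and red blood cells, stress genes, translation, respiration, histones, chromatin regulators and extracellular matrix. Alternatives were other scalings (RLE, upper quartile, total counts), other low-count filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, a test against a change of 1.5-fold, and a smooth (loess, span 0.3) offset for gene length. Added after seeing the data were an offset and a background of similar coding length (20 nearest genes per member), halved counts, an assumed coefficient of variation of 0.2, cameraPR on edgeR statistics, and lists of 24 YAP and TEAD targets, 17 mesothelial genes and 6 pairs of Y- and X-linked genes. Coding and untranslated lengths were those of the transcript with the best APPRIS rank in M21, the longest coding sequence deciding ties. Abundance, where a background was matched on it, was the mean CPM over input and RIP libraries together. Random draws from such backgrounds treated genes as independent.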

Results

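DDX20, also called Gemin3, is a DEAD-box RNA helicase and a member of the SMN complex, which loads Sm proteins onto spliceosomal small nuclear RNAs. RNA that came down with a DDX20 antibody was sequenced from testis cells of 7-day-old C57BL/6 mice, an age at which the tubules hold spermatogonia and dividing Sertoli cells. The cells had been exposed to ultraviolet light, which crosslinks RNA to bound protein. Each of 2 immunoprecipitated libraries (DDX20 RIP) was set against 2 libraries of input RNA, made from 10% of the total RNA. The deposited read counts summed to 21913977 and 21416567 in the input libraries and to 38458014 and 37927689 in the RIP libraries. The comparison asks which RNAs are over- or under-represented in the precipitate. No control precipitation with another antibody was used here, so a higher level means a larger share of the RIP libraries than of the input, not binding by DDX20. It measures recovery only as far as both were made from the same cells, as the labels describe them.

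Genes with long messages led the increases in the precipitate, and RNA made in mitochondria led the decreases. Lrp2, the endocytic receptor megalin, rose most among genes chosen by the naming rule, from 8.19 ± 0.355 to 59.97 ± 1.19 CPM (counts scaled to library size; mean ± SD, n = 2 libraries per group), a 7.32-fold difference. Spen, a transcriptional repressor that binds RNA, rose from 42.9 ± 3.64 to 265.9 ± 9.29 CPM, and Fat1, a giant protocadherin, from 193.3 ± 8.60 to 1107 ± 33.2 CPM. At the other end, mt-Co3, a mitochondrially encoded subunit of cytochrome c oxidase, fell from 784.8 ± 5.87 to 21.02 ± 1.26 CPM. Igf1, a growth factor made by stromal cells, fell from 48.0 ± 3.24 to 5.69 ± 0.397 CPM.

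In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 13461 of 17422 genes passed an adjusted p of 0.05, of which 6734 were higher in RIP and 6727 lower. At least 2-fold differences were called for 2979 genes higher and 4087 genes lower. These counts were 1567 and 5558 with total counts and 1590 and 5531 with upper-quartile scaling. The balance of directions depends on the scaling between libraries: with total counts alone 4994 genes were higher and 8845 lower, and with upper-quartile scaling 5022 were higher and 8798 lower. Those scalings moved the median log2 fold change of all genes from -0.05 to -0.40 and -0.39, and fold changes are given here relative to the scaling by trimmed mean of M values (TMM). Replicates lay close to counting noise, and the labels do not say that they came from separate cell preparations, so the p-values measure a spread that may be technical.

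The other genes among the 10 largest increases were the zinc finger gene Zfp469 (log2 fold change 2.705), Pkhd1l1 (2.60), Fryl (2.51), the laminin chain gene Lama5 (2.44), the zinc finger homeobox gene Zfhx3 (2.43), Dnajc13 (2.41), which encodes an endosomal co-chaperone, and Flnc (2.41), which encodes an actin-crosslinking filamin. Their standard errors ran from 0.0250 for Pkhd1l1 to 0.0822 for Zfp469. Their coding sequences, where the annotation gives one, ran from 6729 nt in Dnajc13 to 13980 nt in Lrp2. Lrp2 (ENSMUSG00000027070.15) lies on chromosome 2 from 69424340 to 69586065, Spen on chromosome 4 from 141467890 to 141538597 and Fat1 on chromosome 8 from 44935447 to 45052257 (GRCm38). Among the 10 largest decreases, mt-Nd3 (-4.60), mt-Atp6 (-4.45), mt-Tp (-4.01), mt-Co2 (-3.77) and mt-Rnr1 (-2.92) are mitochondrial, and Ogn (-3.48), Serf1 (-3.18), Igf1 (-3.08) and Arl5c (-2.90) are nuclear genes. Ogn encodes osteoglycin, a proteoglycan of connective tissue. The largest adjusted p among these 20 genes, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, was 9.44e-18, for Ogn.

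**Figure D1:**
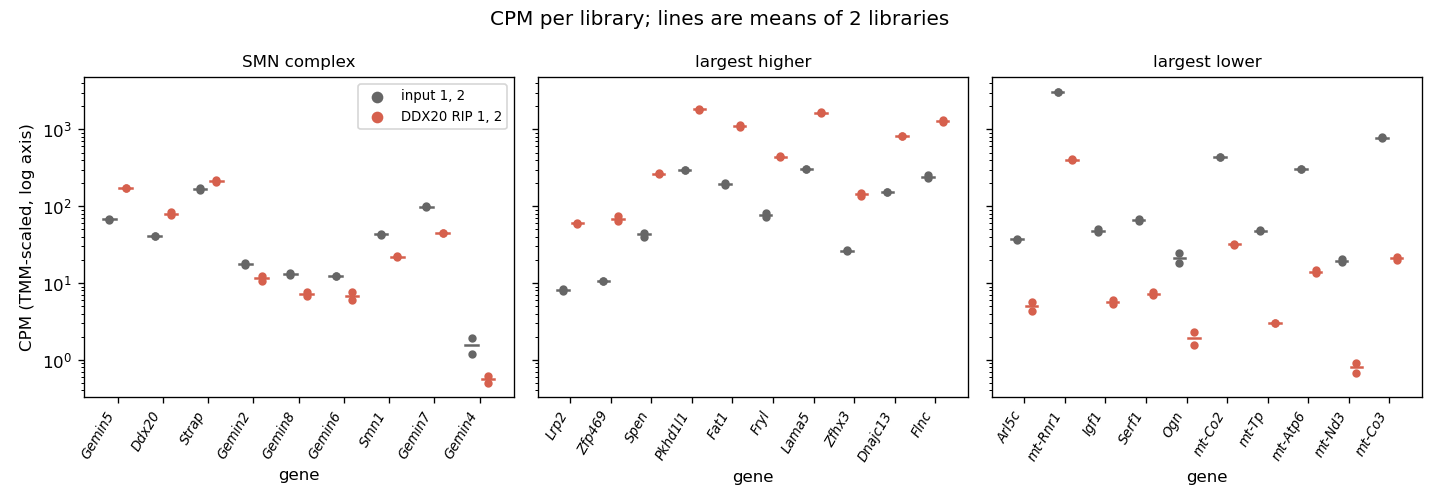
CPM (TMM-scaled, log axis) of the SMN complex genes and of the 10 largest increases and decreases; each point is 1 library, grey for input and red for DDX20 RIP, and each line is the mean of 2 libraries. Replicate points nearly coincide, and mt-Co3 drops from a mean of 784.8 to 21.02 CPM.

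The messages of DDX20's own complex moved in both directions. Gemin5, whose protein recognises small nuclear RNAs, rose by a log2 fold change of 1.36 ± 0.0403 (SE, n = 2 per group), and Ddx20 itself rose by 0.96 ± 0.0552, from 41.3 ± 0.104 to 80.4 ± 3.96 CPM. Strap rose by 0.34 ± 0.0354 with TMM scaling and stood at -0.012 with total counts and -0.0059 with upper-quartile scaling, where it did not pass the test. The other 6 members fell, namely Smn1 (-0.97 ± 0.0719), Gemin7 (-1.15 ± 0.0497), Gemin8 (-0.85 ± 0.125), Gemin6 (-0.86 ± 0.133), Gemin2 (-0.62 ± 0.107) and Gemin4 (-1.45 ± 0.409). The list as a whole was not called (camera adjusted p = 0.442). Ddx20 (ENSMUSG00000027905.16) lies on chromosome 3 from 105678270 to 105687574 and Smn1 on chromosome 13 from 100124852 to 100137690 (GRCm38). Gemin4 stood at 1.54 ± 0.515 CPM in the input and lost its call without input replicate 2 (log2 fold change -1.06). After an offset for coding length, chosen after seeing the data, Ddx20 stood at 0.065, Gemin5 at -0.058, Gemin7 at -0.099 and Gemin6 at -0.044, and none of them passed the test, nor did Gemin2 after an offset for gene length (-0.22).

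Sm and LSm proteins, the ring-forming partners of small nuclear RNAs, were depleted almost throughout. Of 18 members 17 fell and 1 rose, with a median log2 fold change of -1.25. Snrpd2 fell by 1.87 and the more abundant Snrpb fell by 0.30, while Lsm11, a subunit of the U7 particle that processes histone messages, rose by 0.73. The list was called by camera (adjusted p = 7.85e-07, and 0.207 with an estimated correlation). Camera also called it against genes of similar gene length, at a median difference of -0.74 (adjusted p = 0.000401). Against genes of similar coding length it was not called, at a median difference of 0.0085 (adjusted p = 0.0790). Against genes of similar coding length and abundance the median differed by -0.03, with 55.22% of random draws above it. Abundance here is the mean CPM over input and RIP libraries, so RIP values enter it. Mean CPM correlated with log2 fold change (Spearman's rho 0.425), so matching on it can take away part of a list's difference. Among SR proteins and hnRNPs, the factors that steer splice-site choice, 22 of 31 rose and 7 fell, against 15 and 11 with total counts. Hnrnpu rose by 1.12 and Hnrnpk by 0.72, whereas Srsf3 (-0.69) and Hnrnpc (-0.42) fell. This list was called higher (adjusted p = 0.00488; adjusted p = 0.288 with an estimated correlation), and was called against genes of similar coding length (adjusted p = 0.00151) but not of similar gene length (adjusted p = 0.102).

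Small nuclear, small nucleolar and Cajal body RNAs, which are themselves substrates or relatives of substrates of the complex, were mostly rare, with 24 of 124 listed genes tested. Of these 5 rose and 7 fell, and 4 rose and 7 fell when adjusted over the list alone. A tally over all tested genes of these annotated types, made after seeing the data, adds genes with predicted symbols. In it 12 of 31 small nucleolar RNAs rose and 6 fell (10 and 8 with total counts). Of 8 Cajal body RNAs 4 rose and 1 fell (3 and 2 with total counts), and of 7 small nuclear RNAs 1 rose and 3 fell. Over genes of every type, 6734 of 17422 rose and 6727 fell. Snord17 rose from 0.963 ± 0.0434 to 3.61 ± 0.585 CPM and the Cajal body RNA Scarna6 from 0.697 ± 0.0684 to 2.38 ± 0.397 CPM. Snord104 fell from 13.9 ± 0.0632 to 3.07 ± 0.418 CPM, and the Y RNA Rny1 from 7.12 ± 0.356 to 0.857 ± 0.209 CPM. The list was not called (adjusted p = 0.442), but stood higher by 1.55 against genes of similar gene length (adjusted p = 0.0193). That background took genes of any type and did not leave out mitochondrially encoded genes or pseudogenes. Depletion of such genes can make up part of the difference. Most such RNAs lie inside introns or beside other genes, and the kit does not mark strand, so part of these reads can belong to host transcripts.

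Cell cycle genes were enriched more often than depleted. In the G2/M list 36 of 53 genes rose and 13 fell, with a median log2 fold change of 0.94. Top2a, the topoisomerase of dividing cells, rose from 511.2 ± 2.55 to 2409 ± 35.7 CPM and Cbx5, a heterochromatin protein, rose by 1.17. Tubb4b (-0.35) and Jpt1 (-0.68) fell. In the S phase list 26 of 43 rose and 14 fell, and under total counts or upper-quartile scaling 21 rose and 18 fell. The replication helicase subunit Mcm6 rose by 1.55 and the ribonucleotide reductase subunit Rrm1 by 1.53, while the histone chaperone Nasp (-0.51) and the replication clamp Pcna (-0.15) fell. G2/M genes were called higher as a list (adjusted p = 0.000198; adjusted p = 0.207 with an estimated correlation), as were S phase genes (adjusted p = 0.0154; adjusted p = 0.242 with an estimated correlation). Against genes of similar coding length camera called neither (adjusted p = 0.105 and 0.292), at median differences of 0.54 and 0.17. Against genes of similar gene length it called G2/M genes (adjusted p = 0.00582) but not S phase genes (adjusted p = 0.0786). With coding length and abundance both matched, G2/M genes differed by 0.19, above 95.33% of random draws, and S phase genes by -0.11, below 83.08%. Of 21 G1 cyclins, kinases and inhibitors 10 rose and 6 fell, and with total counts or upper-quartile scaling 7 rose and 11 fell. Cdk6 rose by 1.26 and Ccnd2 by 0.57, Cdk4 fell by 0.53 and Cdkn2a by 0.10, and the list was not called (adjusted p = 0.442). Cdkn2a lost its call without any 1 of the 4 libraries, at values from -0.09 to -0.05.

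Germ cell markers moved both ways relative to all genes. Of 14 general germ cell genes 5 rose and 8 fell, with Tex15 (0.81) and Piwil2 (0.18) higher and Tex101 (-1.44) and Tuba3a (-0.37) lower. Piwil2, a partner of piRNAs, stood at -0.16 and -0.17 with upper-quartile scaling and total counts, and lost its call without input replicate 1 (0.27), input replicate 2 (0.12) or RIP replicate 2 (0.14). Among 23 genes of undifferentiated spermatogonia 9 rose and 4 fell with TMM scaling, against 3 and 8 with upper-quartile scaling. Foxo1 rose by 1.08 and Ret by 0.50, though Ret did not pass the test with total counts (0.15), and Nanos3 (-1.98) and Upp1 (-1.54) fell. Of 12 genes of differentiating spermatogonia 3 rose, among them the retinoic acid receptor gene Rarg (1.06) and Ccnd2, and 7 fell, among them the meiotic entry gene Stra8 (-1.30) and Sohlh1 (-0.69). In early meiosis 5 of 16 genes rose, with the cohesin genes Stag3 (1.36) and Rec8 (0.87), and 8 fell, with the synaptonemal complex genes Syce2 (-1.84) and Syce1 (-1.02). None of these 4 lists was called by camera, with adjusted p of 0.148, 0.874, 0.158 and 0.326 in the order given, and at an unadjusted p under 0.05 none of them passed either. Against genes of similar coding length, a background chosen after seeing the data, the general germ cell list was called lower, with a median difference of -0.96 (adjusted p = 0.00679), and 14 of its 14 genes lay below the coding length trend. Tuba3a shares sequence with a near-identical copy and its value is uncertain.

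Markers of somatic testis cells were mostly depleted. All 9 Leydig cell genes tested fell, with the steroid enzyme gene Hsd3b1 at -1.61 and Nr5a1 at -0.12, and the list was called lower (adjusted p = 0.000573; adjusted p = 0.207 with an estimated correlation). Of 19 Sertoli cell genes 14 fell, led in abundance by Clu (-0.67) and Ctsl (-0.30), and 4 rose, among them transferrin, Trf (1.52), and Wt1 (0.70). That list was called lower too (adjusted p = 0.000265; adjusted p = 0.207 with an estimated correlation). Macrophage genes fell in 9 of 11 cases, with Lyz2 at -2.32 and C1qa at -1.47 (adjusted p = 0.00488; adjusted p = 0.288 with an estimated correlation). All 5 red blood cell genes tested fell, with Hbb-bs at -2.11 and Hba-a1 at -1.59, both of which share reads with neighbouring copies (adjusted p = 0.00488; adjusted p = 0.237 with an estimated correlation). Against genes of similar coding length camera did not call the macrophage and red blood cell lists (adjusted p = 0.124 and 0.113), at median differences of -1.22 and -1.30. Nor did it against genes of similar gene length (adjusted p = 0.382 and 0.226), at -0.66 and -0.51. Nr5a1 lost its call without any 1 of the 4 libraries, at values from -0.14 to -0.03.

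Endothelial and stromal genes included members with opposite changes. Of 10 endothelial genes 6 fell, with Cdh5, which encodes VE-cadherin, at -2.32 and Egfl7 at -1.32, and 2 rose, namely the receptor gene Flt1 (1.71) and Vwf (0.68). Of 16 genes of peritubular myoid and stromal cells 9 fell, with Dcn at -0.73 and Col3a1 at -0.58, and 4 rose, with Col1a1 at 1.59 and Col1a2 at 1.04. Camera called neither list (adjusted p = 0.250 and 0.145). Against genes of similar gene length it called both lower (adjusted p = 0.0193 and 0.0378), at median differences of -1.15 and -0.89. Against genes of similar coding length it called the endothelial list (adjusted p = 0.00746) but not the stromal list (adjusted p = 0.184), at -1.44 and -0.76. In the extracellular matrix list, by contrast, 20 of 25 genes rose and 5 fell. Fibronectin, Fn1, rose from 2158 ± 13.6 to 8674 ± 224 CPM and became the most abundant named gene in RIP, while Lama2 fell by 0.30. This list was called higher (adjusted p = 6.13e-06; adjusted p = 0.237 with an estimated correlation), but not against genes of similar gene length (adjusted p = 0.0989) or coding length (adjusted p = 0.713). Vwf lost its call without input replicate 1 (0.48) and with total counts (0.34), and Lama2 without input replicate 2 (-0.25).

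Cytosolic ribosomal protein genes and genes of respiration were depleted. All 87 cytosolic ribosomal protein genes fell, with a median log2 fold change of -1.35, and the most abundant members were Rplp0 (-1.06) and Rpsa (-0.88). Genes of similar coding length and abundance had a median of -1.08, from which the list differed by -0.27. Reads of this family are shared with many processed pseudogenes. Of 81 nuclear-encoded genes of oxidative phosphorylation 76 fell and 3 rose, and the list differed by -0.59 from such genes. Cox6a1 fell by 1.49 and Atp5b by 0.06, while Sdha rose by 0.93 and Atp5a1 by 0.11 with TMM scaling, against -0.24 for Atp5a1 with total counts. Atp5b lost its call without any 1 of the 4 libraries, at values from -0.050 to -0.016. All 21 mitochondrially encoded genes tested fell, with a median of -2.92. Their share of all counts was 2.59% and 2.57% in the input libraries and 0.34% and 0.35% in the RIP libraries. Ribosomal, respiratory and mitochondrial lists were called lower, at adjusted p = 2.38e-38, 1.61e-24 and 1.67e-11 (adjusted p = 0.207 with an estimated correlation for each). Within the mitochondrial list, mt-Co1 fell by 2.54 and the ribosomal RNA mt-Rnr2 by 2.89, and nuclear copies of these genes can share their reads. Translation initiation and elongation factors split, with 26 of 69 higher and 39 lower. Eif4g1 (1.91) and Eef2 (0.76) rose, Eef1b2 (-1.17) and Eef1g (-0.36) fell, and the list was not called (adjusted p = 0.259).

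Chromatin regulators formed the most uniformly enriched list. Of its 50 genes 48 rose, with a median log2 fold change of 1.53, and the remodeller genes Chd4 and Smarca4 each rose by 1.93. Tet1 (-1.10) and Dnmt3l (-1.27) fell, from 3.83 ± 0.202 and 0.718 ± 0.214 CPM in the input, and Dnmt3l lost its call without input replicate 1 (-1.52), input replicate 2 (-0.93) or RIP replicate 2 (-0.75). Camera called the list higher (adjusted p = 8.01e-16; adjusted p = 0.237 with an estimated correlation). Its median exceeded that of genes of similar coding length by 0.27 (adjusted p = 0.00272), and against genes of similar coding length and abundance it differed by -0.10, below 91.83% of 10000 random draws. Of 52 replication-dependent histone genes 21 fell and 1 rose, and 16 fell and 0 rose when adjusted over the list alone. With total counts 35 fell and 0 rose. Hist1h1c (-0.28) and Hist1h1e (-0.34) fell, and Hist1h1a stood at 0.19 with TMM scaling and at -0.16 with total counts. These genes are near-copies of each other, so their single values are uncertain. Each of these 3 genes also lost its call without 3 or 4 of the libraries left out in turn, at values from -0.26 to -0.21 for Hist1h1c, -0.35 to -0.25 for Hist1h1e and 0.12 to 0.24 for Hist1h1a. The histone list was called lower (adjusted p = 0.0276; adjusted p = 0.237 with an estimated correlation). Against genes of similar length the histone call turned higher, by a median difference of 0.71 in log2 fold change (adjusted p = 0.0193).

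Noncoding host genes and stress genes completed the lists. All 13 host genes of small nucleolar RNAs tested fell, with Snhg18 at -2.03 and Gas5 at -1.44 (adjusted p = 0.000375; adjusted p = 0.207 with an estimated correlation). Among 11 nuclear-retained long noncoding RNAs Neat1 (1.13) and Firre (0.91) rose, and 3 fell, against 7 with total counts, with Malat1 at -1.26 and Rian at -1.51. After an offset for gene length Neat1 (0.017) and Firre (0.24) did not pass the test. Of 19 immediate early and heat shock genes 11 rose and 4 fell with TMM scaling, against 4 and 10 with total counts. Hsp90aa1 rose by 0.90, Hspa8 stood at 0.32 with TMM scaling and -0.03 with total counts, and Hspb1 (-0.80) and Ier2 (-0.35) fell. Camera called neither of the last pair of lists (adjusted p = 0.485 and 0.337). Against genes of similar gene length it called the nuclear-retained RNAs lower, with a median difference of -1.12 (adjusted p = 0.00113). That background took genes of any type, and 14677 of 17422 genes tested are protein-coding. The list's median was -0.33, against -1.08 for all long intergenic noncoding RNAs tested, whatever their length. The listed RNAs are long, with a median merged exon length of 8756 nt, and no background of noncoding RNAs of similar length was run. Whether the call is particular to nuclear-retained RNA is therefore not known.

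Across the 27 lists camera, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment, called 5 higher and 10 lower. With an estimated correlation camera called 0, and 4 lists passed an unadjusted p of 0.05. Only 2 residual degrees of freedom remain in that setting. The estimate also exceeded the preset for some lists, as at 0.179 for chromatin regulators and 0.137 for mitochondrial genes. For others it lay under the preset, as at -0.028 for Leydig cells. With total counts 2 germ cell genes rose and 9 fell, as did 4 and 10 in early meiosis, 2 and 16 in Sertoli cells, 2 and 12 in stromal cells, 1 and 8 in endothelial cells, 4 and 9 among small RNAs and 20 and 44 among translation factors. For 25 of the 27 lists the counts of higher and lower genes were the same adjusted over the list alone as over all genes.

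**Figure D2:**
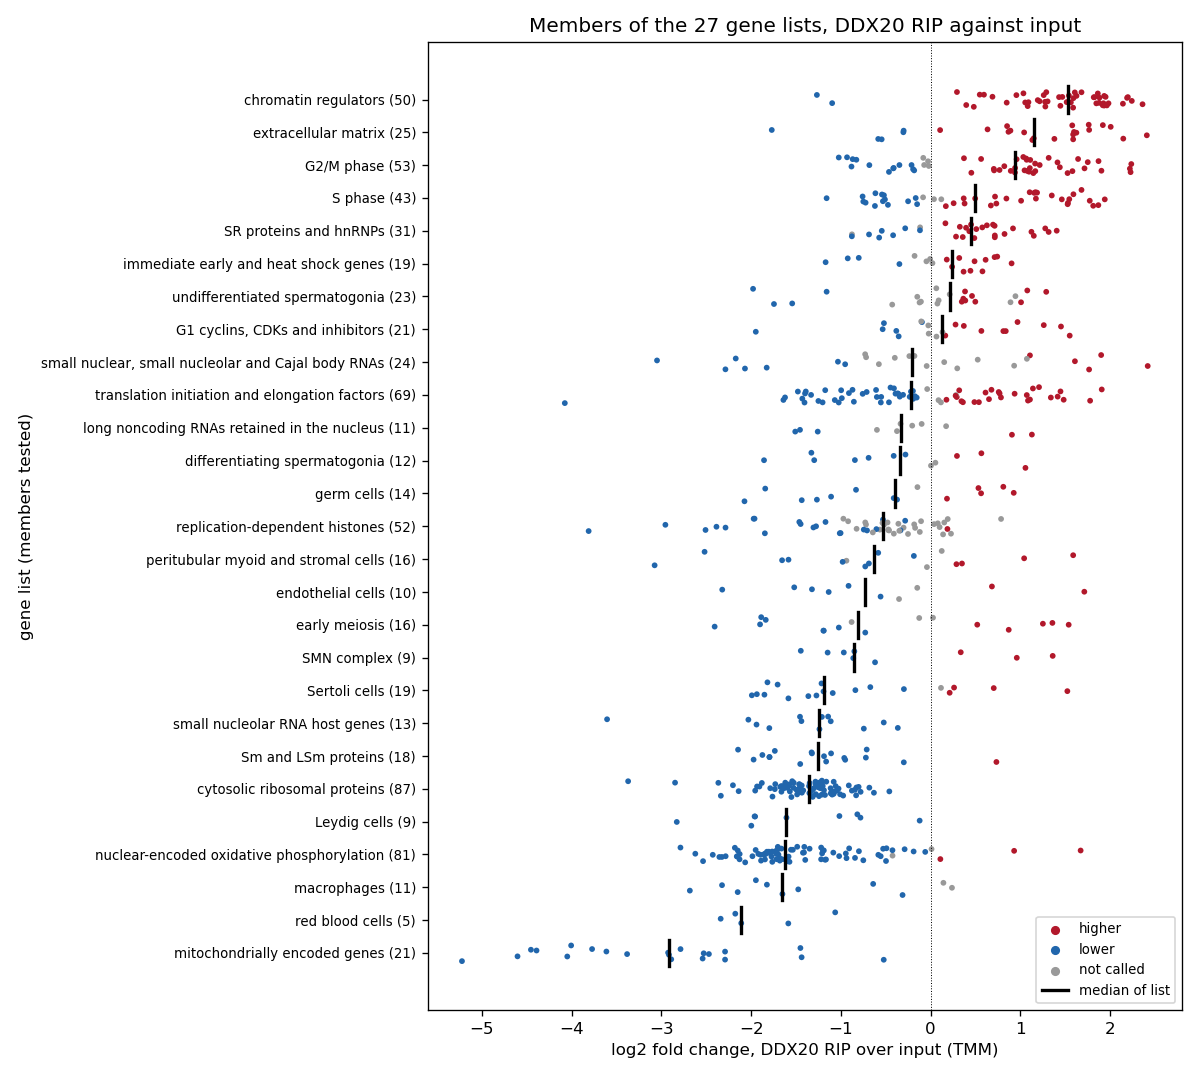
Log2 fold change of every tested member of the 27 lists (number tested in brackets); points are genes, red where called higher, blue where called lower and grey where not called, and the black bar is the list's median. Medians run from -2.92 for mitochondrially encoded genes to 1.53 for chromatin regulators.

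Longer genes were more enriched. Across 17357 genes with a length, the Spearman correlation of merged exon length with log2 fold change was 0.557, and it lay between 0.543 and 0.552 in each of the 4 single pairs of a RIP with an input library. Genes in the shortest length quintile had a median log2 fold change of -1.33 and those in the longest of 0.81. In the shortest quintile 72.2% of genes were lower and 5.96% higher, and in the longest 14.4% were lower and 70.0% higher. These are descriptions across genes, which are not independent replicates.

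Within 14660 protein-coding genes, a division chosen after seeing the data, the coding sequence carried more of this trend than the untranslated ends. Spearman's rho was 0.637 for coding length, 0.264 for the 3' untranslated region and 0.144 for the 5' untranslated region. Median log2 fold change went from -0.99 in the quintile with the shortest coding sequences (75 to 732 nt) to 1.16 in that with the longest (2496 to 100401 nt), and from -0.55 to 0.43 between the outer quintiles of 3' untranslated length. Chromatin regulators, the list with the highest median, have a median coding length of 5278.5 nt, and cytosolic ribosomal protein genes one of 453 nt. After a smooth offset for gene length 1866 genes were at least 2-fold enriched, and after one for coding length 585.

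**Figure D3:**
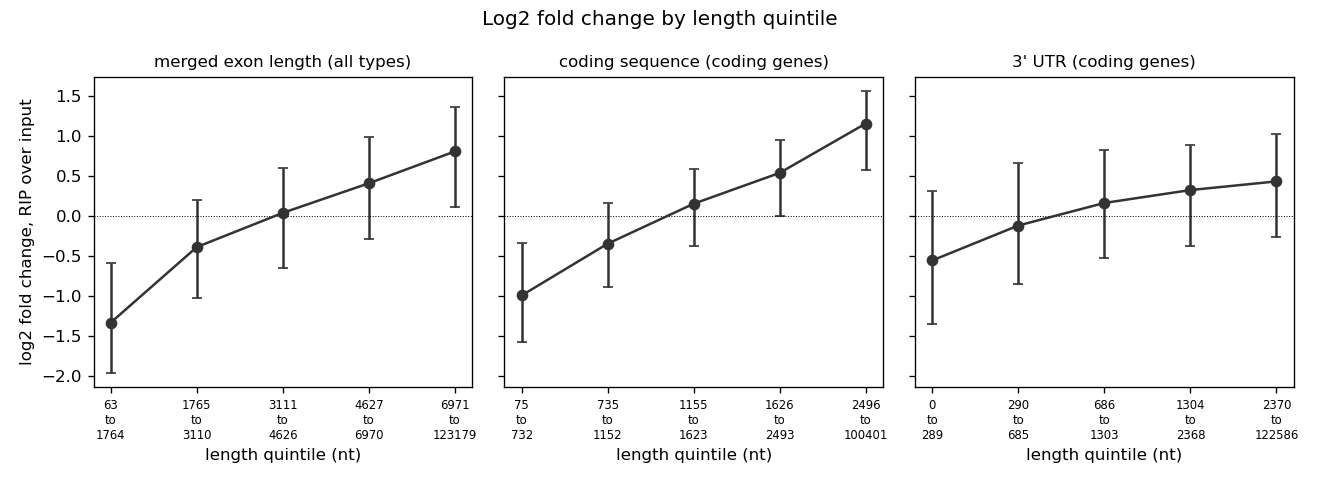
Median log2 fold change (points) with the interquartile range (bars) in 5 length classes, for merged exon length of all gene types, coding sequence and 3' untranslated region of coding genes; class limits in nucleotides are on the x axis. The median rises from -0.99 to 1.16 over coding length and from -0.55 to 0.43 over 3' untranslated length.

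Processed pseudogenes, long intergenic noncoding RNAs and antisense genes were mostly depleted, and small nucleolar and Cajal body RNAs were not. Of 993 processed pseudogenes 700 fell and 53 rose, of 478 long intergenic noncoding RNAs 252 fell and 66 rose, and of 391 antisense genes 228 fell and 28 rose. Of 31 small nucleolar RNAs 12 rose and 6 fell, with a median log2 fold change of 0.66 (0.32 with total counts). Most of them were rare, and the one that rose most, Gm26448, had a mean CPM of 0.712. Genes this rare can pass the low-count filter through the group where they are high. Of 8 Cajal body RNAs 4 rose and 1 fell, with a median of 0.97 (0.63 with total counts). Of 7 small nuclear RNAs 1 rose and 3 fell, with a median of -0.04. At a mean CPM of at least 1, 212 long intergenic noncoding RNAs had a median of -0.96, against -0.70 in coding genes of matched exon length and abundance. Processed pseudogenes share sequence, and so reads, with their parent genes, and without strand the reads of antisense genes cannot be told apart from those of their partners.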

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

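The coding length offset and background, halved counts, assumed coefficient of variation and cameraPR were chosen after seeing the data. The count of called genes stayed within 1.5 times of 13461 under every scaling, filter and tool run, from 9806 with an assumed coefficient of variation of 0.2 to 13839 with total counts, and was 8636 when tested against a change of 1.5-fold. Without 1 library it was 11337 to 12384. Genes at least 2-fold enriched numbered 2979, 2941 to 3140 without 1 library, 1590 with upper-quartile scaling, 1567 with total counts, 1866 with the gene length offset, 1854 with that offset and the replicate block, and 585 with the coding length offset, which tested 14660 genes. The rank correlation with gene length was 0.616 at a mean CPM of at least 10.

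Deviations from the group means correlated at -0.001 between same-numbered libraries. Replicates lay close to counting noise, so this value cannot show whether replicate numbers paired the libraries. With the replicate block 13389 genes were called, 2969 at least 2-fold enriched, and all 116 named genes kept their direction and call.

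Of 27 lists, 15 were called, 15 with the replicate block and 14 against genes of similar gene length. Against genes of similar coding length 9 were called (not run for mitochondrial genes, small RNAs, nuclear-retained RNAs and small nucleolar RNA host genes). Fry called 25, but it asks whether a list changed at all, not whether it changed more than other genes. With 13461 of 17422 genes called, that count is no check on camera's. Camera with an estimated correlation called 0. Leaving out a library gave 0 to 15: 15 without either input library, and 0 without RIP replicate 1 or RIP replicate 2. With 1 RIP library the voom fit collapsed, its moderated statistics having quartiles of -0.0140 and 0.0234 (without RIP replicate 1) beside a smallest value of -648, and cameraPR on edgeR statistics called 14 and 14 lists there and 15 with all libraries. The test's direction turned for undifferentiated spermatogonia (median 0.21) with fry and the block and against similar coding length (0.088), for translation factors (-0.22) with fry, for histones against similar gene length (0.71) and coding length (0.42), and for small RNAs against similar gene length (1.55).

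Leaving out 1 library kept direction and call of 105 of the 116 named genes. The other 11, which lost the call, were Dnmt3l, Vwf, Lama2, Atp5b, Nr5a1, Piwil2, Cdkn2a, Gemin4, Hist1h1a, Hist1h1c and Hist1h1e. With an assumed coefficient of variation of 0.2, 25 lost the call, among them Ccnd2, Cdk4, Ctsl, Col3a1, Pcna, Snrpb, Tubb4b and Hnrnpc; 8 lost it with DESeq2, 7 with the gene length offset, 4 of 97 with the coding length offset, 6 with no low-count filter, 3 with RLE, 3 with a CPM filter, 2 with upper-quartile scaling, 2 with total counts, 2 with halved counts and 0 with limma-voom. Log2 fold changes of 26 named genes changed sign under some setting. With upper-quartile scaling and total counts these were Hspa8 (-0.023, -0.029), Atp5a1 (-0.23, -0.24), Strap (-0.0059, -0.012), Piwil2 (-0.16, -0.17) and Hist1h1a (-0.15, -0.16). The length offsets subtract the trend, so a change of sign there means only that a gene lies on the other side of the trend. With the gene length offset, without and with the replicate block, they were Ccnd2 (-0.18, -0.18), Vwf (-0.34, -0.33), Hspb1 (0.45, 0.45), Pcna (0.26, 0.26), Snrpb (0.33, 0.33), Ret (-0.00544, -0.00548), Piwil2 (-0.16, -0.16), Hist1h1c (0.58, 0.58), Tubb4b (0.21, 0.21), Cox6a1 (0.10, 0.10), Cdkn2a (1.03, 1.03), Hist1h1e (0.32, 0.32), Ier2 (0.54, 0.54), Gemin6 (0.083, 0.078), Sohlh1 (0.35, 0.35) and Tuba3a (0.52, 0.52). With the coding length offset they were Vwf (-1.08), Tex15 (-0.95), Hspa8 (-0.31), Jpt1 (0.21), Atp5a1 (-0.33), Pcna (0.24), Snrpb (0.20), Col1a2 (-0.31), Ret (-0.70), Piwil2 (-0.89), Eef2 (-0.18), Hist1h1c (0.30), Gemin5 (-0.058), Cdkn2a (0.71), Hist1h1e (0.21), Ier2 (0.19) and Srsf3 (0.14). The causes of the other changes were not tested. With no low-count filter 30658 genes were tested and 13173 called. Depth limits what a count of 0 can show: with 3 read pairs, or 6 counts, as the limit, it allows up to 0.243 and 0.248 CPM (TMM-scaled) in the input libraries and 0.177 CPM in each RIP library, counting error only.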

Other observations

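The noncoding, Y-linked, added-list and coding-trend results here were chosen after the fold changes had been seen, as were the tests of GC content, of gene length for mitochondrial genes and of Y-linked genes, and the matching on abundance of YAP and TEAD targets and of lists beyond the 4 chosen for that test. Y-linked genes behaved unlike their X-linked partners. Ddx3y, the Y copy of an RNA helicase gene, fell from 11.7 ± 0.808 to 6.71 ± 0.376 CPM (mean ± SD, n = 2), while Ddx3x rose from 371.7 ± 0.997 to 633.2 ± 12.2 CPM. Eif2s3y fell from 15.3 ± 0.437 to 5.66 ± 1.07 CPM and Kdm5d, Uty and Uba1y also fell, by 0.84, 1.11 and 0.57 on the log2 scale; Usp9y alone of the 6 rose, by 0.55, against 2.20 for Usp9x. The Y copy stood at 21.8% of the X copy for Eif2s3 in the input and 5.30% in RIP, and at 3.16% and 1.06% for Ddx3. Over the 6 pairs it ran from 1.71% (Usp9y) to 23.4% (Uty) in the input, and from 0.544% (Usp9y) to 7.17% (Uty) in RIP. Xist, the RNA that coats an inactive X chromosome, had 0 counts in each of the 4 libraries, which allows up to 0.243 and 0.248 CPM in the input libraries and 0.177 CPM in each RIP library (3 read pairs counted as 6, TMM-scaled, counting error only).

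Several mesothelial genes were abundant in both kinds of library, while 7 of the 17 listed stood under 10 CPM in the input, among them Krt7 (0.697 CPM) and Muc16 (1.32 CPM). Upk3b stood at 622.0 ± 11.8 CPM in the input and 794.7 ± 21.7 CPM in RIP, Krt19 at 773.6 ± 8.31 and 1126 ± 11.2 CPM, and Msln at 263.1 ± 3.31 and 617.2 ± 1.22 CPM. Of 17 mesothelial genes 10 rose and 3 fell, and 9 lay above and 1 below their coding length trend by edgeR's test. The list was written after several of its members had been seen, and Wt1 is also a Sertoli cell gene. Against coding genes of similar coding length and abundance the list's median lay 0.40 higher in log2 fold change, above 96.59% of 10000 random draws of such genes. Extracellular matrix genes split around the coding length trend, with 11 called above it, among them Fn1, Col4a1, Tnc and Sparc, and 12 below it. Against coding genes of similar coding length and abundance their median lay lower, by -0.57, below 100% of draws. That abundance includes RIP values, so for a list with high RIP values the matching itself can lower the difference. Of 19 Sertoli genes 14 lay below the trend and 3, Wt1, Trf and Defb19, above it.

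The rise of log2 fold change with coding length was the widest pattern. After thinning every library to 21416567 counts Spearman's rho was 0.650. Thinning finished counts keeps the expected ratios between libraries, so rho could hardly have fallen and this cannot exclude an effect of deeper sequencing. GC content did not account for the trend, as rho for coding length given GC content was 0.639. Recovery set by RNA length alone, through loss of short RNA or more crosslinks on long RNA, may contribute: over 212 long intergenic noncoding RNAs the rho of exon length was 0.364 (95% bootstrap interval 0.239 to 0.476), against 0.474 (0.359 to 0.574) in matched coding genes, and an interval this wide keeps the explanation open. No biological explanation was tested, because without a control precipitation selective binding and unselective recovery of long messages leave the same trend.

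Mitochondrially encoded RNA fell further than other genes of its length. Short gene length does not account for the loss, because against genes of similar length the median difference was still -1.59 (camera adjusted p = 6.35e-06). After thinning, 95.2% of the 21 genes were still called lower, so the calls do not rest on the extra counts of the RIP libraries. Thinning keeps the expected fold changes, so it cannot test any other effect of depth. No biological explanation was tested, and the sharing of reads with nuclear copies stays open.

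Markers of the 6 testis cell types put to this test, and Y-linked genes, were low for their coding length and abundance. Short coding sequences or low abundance do not account for this: the 4 sets chosen for the test, Leydig, Sertoli, endothelial and Y-linked genes, had medians below those of similar coding genes by -1.53, -1.18, -1.22 and -1.21, each below at least 99.7% of 10000 random draws, and macrophage (-1.21), stromal (-0.90) and germ cell genes (-0.89), like oxidative phosphorylation genes (-0.59), lay lower too. Camera also called the Leydig, Sertoli and endothelial lists lower against genes of similar coding length alone (adjusted p = 0.00679, 0.00679 and 0.00746). For these lists only the matching on abundance is new, and the Y-linked genes were chosen after their values were seen. The lists of germ cell stages were not put to this test. Against genes of similar coding length alone, camera called none of them (adjusted p = 0.792, 0.216 and 0.0625). Their medians differed by 0.09 for undifferentiated spermatogonia, -0.30 for differentiating spermatogonia and -1.24 for early meiosis. More RNA from cells without Y-linked expression in the RIP libraries than in the input could not be tested independently. The value at hand was a median of -1.80 for Y-linked genes minus their X-linked partners relative to the coding length trend. It comes from the genes that raised the idea. A different cell state, as in culture, stays open too. The 22 YAP and TEAD targets had a median of 0.455 above the coding length trend, with 14 called above it and 6 below. This met a criterion written before the list's values were looked up, though single members had been seen. Against genes matched on abundance as well, a check chosen afterwards, their median lay only 0.06 higher, above 59.94% of draws. RIP values entered that abundance, so this check can understate a rise. The labels describe both groups as the same testis cells and name no sort. The cells behind the RIP and input libraries may nonetheless have differed in mix, state or origin, a cell line included. Every fold change here would then hold that difference beside recovery, and no test here decides it. Low Y-linked levels, 0 counts of Xist and abundant mesothelial genes were also found in the input. Whether the input itself matches its label is therefore open too, and the testis cell lists are read on that label.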
